A study of Drosophila melanogaster with 3 samples.

How the data were processed

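Peaks of Senseless-GFP were measured by chromatin immunoprecipitation with an antibody against GFP in 3 biological replicates of whole transgenic Drosophila melanogaster embryos, 4 to 14 hours old and of mixed sex. Per the labels, chromatin was sonicated to 200 to 800 bp. The labels give each replicate's number and no second condition, so all 3 samples form 1 group and no test between conditions was possible. The age field of the labels holds an impossible value, and the collection window was taken from the source description. The aligner and peak caller are not given in the sources used here.

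The analysis started from 10 deposited peak lists in narrowPeak format: 1 per replicate, 1 from the pooled replicates and 1 optimal IDR list, each on the dm6 and dm3 builds. Peaks were thus called by the authors both per sample and on pooled samples. Each deposited peak carries a signal value, a score whose scale is not stated, a −log10 q-value and the offset of its summit from the peak start; the p-value column is empty (−1) throughout. Per the deposited text notes, a control was among the inputs of the dm3 replicate and pooled lists, and no control is listed for the dm6 lists. Replicates 1 and 2 have exactly 30000 peaks on dm6, which looks like a cap, so lists were compared on their 3811 strongest peaks, the number of peaks in the dm6 optimal IDR list. That list is exactly the 3811 strongest peaks of the pooled list of 28357. At a q-value of 0.01, the replicate lists hold 4384, 6319 and 4482 peaks. The median peak width is 424 bp in the IDR list, and 3799 of its 3811 intervals are distinct, since some intervals carry more than 1 summit. Library depth is unknown, and so is the precision that depth would give; binomial intervals cover counting error over peaks only.

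The dm6 lists were the main data. Positions are 1-based on dm6. Genes came from the Ensembl annotation release 115 of the same assembly (13945 protein-coding genes on arms 2L, 2R, 3L, 3R, 4 and X), whose gene starts are the same as those of RefSeq for 99.99% of genes, and sequence from the RefSeq FASTA. No position was converted between builds. A promoter summit lies within 500 bp of any annotated transcript start; other summits were assigned in the order 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Chance placement came from 1000 circular shifts of the summits within each arm (two-sided permutation p, smallest value 0.002). A peak was shared where its summit lay inside a peak of the other list.

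Motifs were searched on both strands within 50 bp of the summit and in equal windows centred 500 bp to each side, with an exact two-sided McNemar test of the summit against a randomly drawn flank, Benjamini-Hochberg adjusted over 10 motifs, and by the rank of AAATCA among its 30 rearrangements. For 20 gene lists, members with a reproducible summit in their territory (gene body plus 5 kb on each side) were counted against 100000 random lists of protein-coding genes matched on length in 20 bins (two-sided permutation p, Benjamini-Hochberg over the 20 lists). Peak density on X was compared with that on 2L, 2R, 3L and 3R by an exact conditional binomial interval. The lists, motifs, windows, tests and most alternatives were fixed before the data were examined.

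The text names the gene for each of the 20 strongest reproducible peaks, being the protein-coding gene whose territory holds the summit, or the gene with the nearest transcript start where more than 1 gene or none does. It also names up to 4 members with the strongest peaks in each list that passed, 11 genes whatever their value (sens, rho, rpr, hid, ac, sc, ase, ato, E(spl)m8-HLH, fkh and CrebA), and the 5 genes with most summits, with the gene tied for the last place. A single gene among those selected is not reported here. Where the nearest start of any transcript belongs to another gene than the one selected, the text says so.

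The tests were tried on 20 simulated sets of 3811 peaks without any effect and 20 with planted effects. Without effects, the promoter test called 0 sets, the motif test 1 set and the list test 3 of 400 lists. With 30% of summits planted at transcript starts, 10% planted on AAATCA or peaks planted in 80% of a list of 24 genes, all 20 sets were called by the respective test, and AAATCA ranked 1 among its rearrangements in all 20. All other simulated summits lay at random positions, without the low GC content of the real summits or their gathering at transcript starts. The simulations thus do not show how the motif and list tests behave on such peaks. Alternatives covered the dm3 lists, the number of strongest peaks, the overlap rule, stricter lists, each replicate alone or left out, windows, transcripts, flanks, territories and matching. Outside the comparisons between replicates, leaving a replicate out meant keeping only the reproducible peaks found among the strongest of both other replicates. Those peaks were still called with all replicates pooled. Added after the data were seen were GC-matched random positions, dinucleotide shuffles, lists with overlapping territories counted once, lists matched also on the number of transcript starts, a 5 kb window around sens and a count of all 8-mers at summits. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.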

Results

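Senseless is a zinc finger transcription factor that acts in the precursor cells of the fly's sensory organs and in the embryonic salivary gland. Its binding was measured by chromatin immunoprecipitation and sequencing in transgenic Drosophila melanogaster embryos of mixed sex, collected 4 to 14 hours after egg laying, that carried Senseless fused to green fluorescent protein (GFP). An antibody against GFP pulled down the fusion protein from whole embryos. The series holds 1 group of 3 biological replicates, so it contains no contrast between conditions, and the comparisons that follow ask where the peaks lie, how far the replicates share them and which genes and sequences they mark. Replicate lists held 30000, 30000 and 27681 peaks on the dm6 build. The authors' list of peaks that passed their irreproducible discovery rate (IDR) threshold held 3811 peaks, called reproducible peaks here. The depth of each library is unknown, since only peak lists were used. Signal values are the authors' scores per peak, on a scale that is not stated. Apart from an alternative correlation on their log scale, they serve to rank peaks within a list and to compare ranks between replicates; where they are summed around genes, the sum is given as a percentile within the same list.

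The strongest reproducible peaks were found at the same genes in each replicate. The strongest of all, with a signal value of 3051, had its summit at 2L position 481057 (dm6), in an intron. It lay inside the gene ush and 1369 bp upstream of the nearest start of cbt, which encodes a zinc finger transcription factor. It ranked 1, 1 and 3 in replicates 1, 2 and 3. The next was at 2R position 22514306, inside px, a gene needed for wing vein patterning, and 207 bp upstream of a px transcript start, with a signal value of 2957 and rank 2 in every replicate. The third lay 27 bp upstream of Ugalt, the Golgi transporter of UDP-galactose, at X position 2703879, with a signal value of 2778. Across the genome, 2451 of the 3811 reproducible peaks (64.3%, exact 95% interval 62.8 to 65.8) had their summit inside one of the 3811 strongest peaks of all 3 replicates.

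Of the 20 strongest peaks, 12 lay within 500 bp of an annotated transcript start, 5 in introns and 3 between genes. All 20 were among the 3811 strongest of every replicate, and the lowest rank that any of them took in a replicate was 34. Besides px and Ugalt, peaks near transcript starts of their assigned gene marked CG14100, Chro (a chromatin protein of interbands and the spindle), ph-p (a Polycomb group gene), CG1888, mRpL41 (a mitochondrial ribosomal protein), CenG1A, CG9147, Tcs5 and PNPase. The peak assigned to hll lay nearest to the start of a long non-coding RNA, 2919 bp from hll itself. Intronic peaks marked CG11050, Lk6 (a kinase of the translation factor eIF4E), cno (a junction protein) and HmgZ (an HMG-box protein). The intergenic peaks were assigned to CG13323, CG31668 and tara, at 11908, 3765 and 3157 bp from the nearest start of each; the last lay nearest to the start of a long non-coding RNA.

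Each replicate's 3811 strongest peaks held 84.4% ± 2.6 (SD, n = 3 replicates) of the reproducible peaks. Between pairs of replicates, 74.4% ± 2.0 (SD, 3 pairs that share replicates) of these strongest peaks coincided, against 1.05% after circular shifts along the chromosome arms (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). Of the remaining reproducible peaks, 953 were among the strongest of 2 replicates, 393 of 1 and 14 of none. Of the 952 peaks with the highest signal, 98.8% were among the strongest of all 3 replicates, and of the 953 with the lowest, 8.92%, a decline that the common limit of 3811 peaks largely sets. The replicates' full lists held 99.5% ± 0.18 (SD, n = 3) of the reproducible peaks. The reproducible list is the top of the pool of these same replicates, so its shares in their lists are partly set by how it was made. At the 3758 reproducible sites with a peak in all 3 replicates, signal ranks correlated across peaks with a mean Spearman rho of 0.71 ± 0.03 (SD, 3 pairs), and peaks are not independent replicates. The share found in all 3 replicates follows the number of peaks taken: it was 34.5% with 50% of that number, which by construction limits it to about 50%, and 92.8% with 2 times that number.

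**Figure D1:**
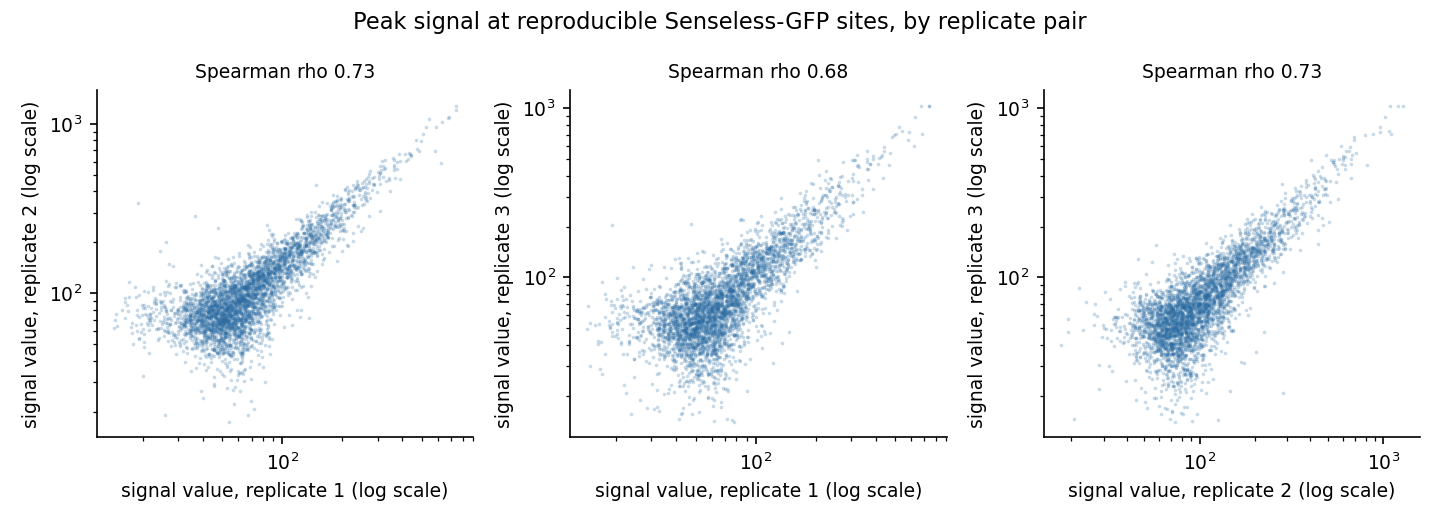
Signal value of each reproducible peak in one replicate against another, both axes on a log scale, with 1 point per peak that has a counterpart in both lists. Spearman rho was 0.73 for replicates 1 and 2, 0.68 for 1 and 3 and 0.73 for 2 and 3, and the points lie closest together at high signal.

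Transcript starts carried the peaks far more often than other parts of genes. Of the 3811 summits, 1855 (48.7%) lay within 500 bp of a transcript start, against 13.6% of shifted summits (95% range 12.3 to 15.1; two-sided permutation p = 0.002). Coding exons outside that window held 4 summits (0.105%), against 13.7% after shifts, and 3' UTRs held 25 (0.656%), against 4.41%. Introns held 1346 summits (35.3%) and intergenic sequence 528 (13.9%), both below their shifted shares of 39.5% and 27.3%. After Benjamini-Hochberg adjustment over the 7 classes, the permutation p was 0.0035 for promoters, coding exons, 3' UTRs and intergenic sequence and 0.00559 for introns, while 5' UTRs (20 summits, adjusted p = 0.0932) and other exons (33 summits, adjusted p = 0.797) did not pass.

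The same placement was seen in each replicate's own list, with 49.2% ± 0.97 (SD, n = 3) of the strongest 3811 summits at transcript starts and 0.192% ± 0.099 in coding exons. Of the reproducible peaks among the strongest of all 3 replicates, 48.6% lay at transcript starts, and of the rest 48.8% (Fisher's exact test, odds ratio 0.995, p = 0.946). That split largely follows signal rank, so it does not measure whether promoter peaks are more reproducible than others. In all, 2287 of 13945 protein-coding genes (16.4%) had a summit within 500 bp of a start of their own.

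**Figure D2:**
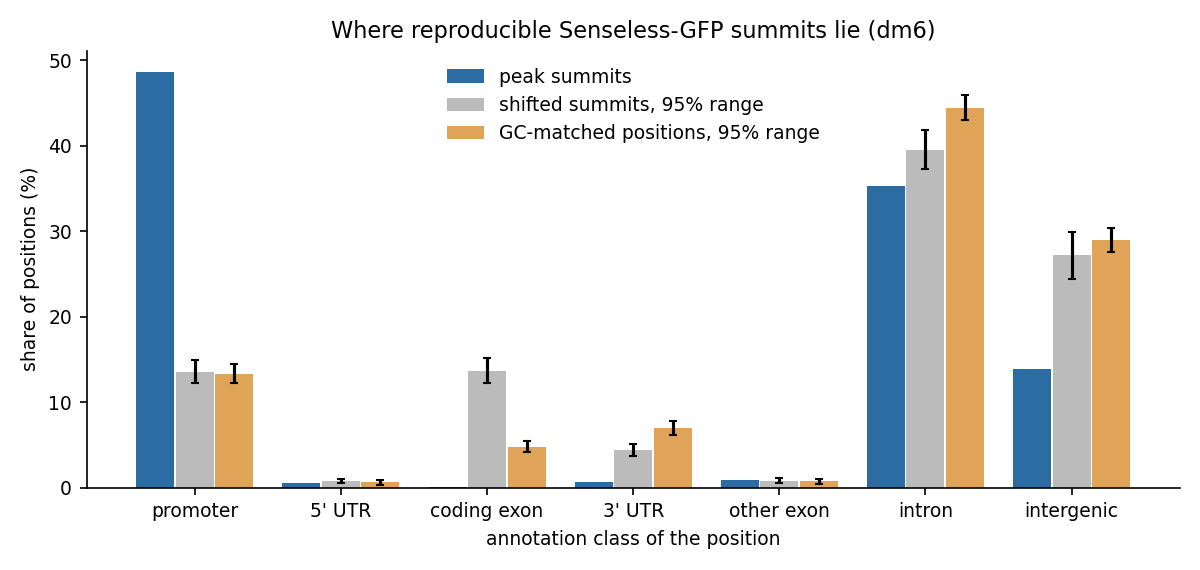
Share of positions, in percent, in each annotation class for the 3811 reproducible summits, for summits shifted along their arm and for random positions of matched GC content; error bars are 95% ranges over 1000 sets. Summits stand at 48.7% in promoters and 0.105% in coding exons, against 13.6% and 13.7% after shifts.

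The 6-base core of the Senseless site, AAATCA, was present within 50 bp of 540 summits (14.2%, exact 95% interval 13.1 to 15.3) and in 9.91% of windows of the same size 500 bp to either side. The difference of 4.26 percentage points passed an exact two-sided McNemar test against a randomly drawn flank (adjusted p = 2.7e-08, Benjamini-Hochberg over 10 motifs). In the replicates' own lists the share was 14.1% ± 0.58 at summits and 10.2% ± 0.33 in flanks (SD, n = 3). The core did not stand out from other 6-mers of the same letters, though. Among the 30 rearrangements of AAATCA it ranked 20 by gain at summits, where the median gain of the other 29 was 4.71 points and the highest, of CAAATA, was 8.83. Against shuffles that keep each summit window's dinucleotides, a comparison added after the data were seen, AAATCA was at 14.2% observed and 13.9% shuffled (permutation p = 0.594), so the gain over flanks was lost there.

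Summit windows were rich in A and T. Their GC content averaged 34.3%, against 43.6% in the flanks, and it was lower than in the flanks at 77.9% of peaks. The 952 peaks with the highest signal averaged 32.4% and the 953 with the lowest 35.8%, while the core motif stood at 14.5% and 14.6% at summits and at 9.4% and 10.9% in flanks of these sets. Of the other sites searched, the GATA site AGATAA (8.003% at summits, 5.62% in flanks, adjusted exact p = 7.88e-06) and the Exd-Hox site (4.04% and 2.56%, adjusted p = 0.00671) were more frequent at summits. The proneural E-box, bound by Achaete, Scute and their partners, was less frequent (3.88% against 6.39%, adjusted p = 6.85e-07), as were any E-box (35.3% against 41.7%, adjusted p = 2.7e-08), the GAGA repeat (10.2% against 14.3%, adjusted p = 3.36e-06) and the Notch effector site of Su(H) (0.577% against 1.21%, adjusted p = 0.007), all by exact McNemar tests. The extended Senseless site was found at 11 summits (0.289% against 0.118%, adjusted exact p = 0.233), the Zelda site at 81 (adjusted p = 0.0776) and the Grainyhead site at 4 (adjusted p = 1), and none of these passed. Apart from the core motif, these motifs were not compared with rearrangements, so base composition enters each of their differences.

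**Figure D3:**
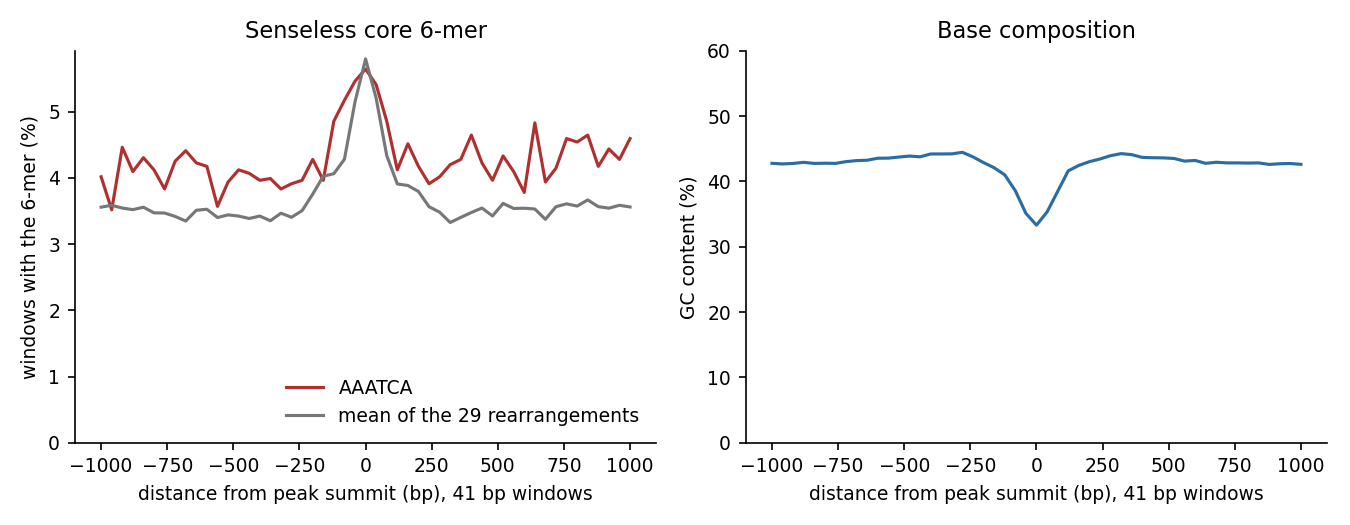
Share of 41 bp windows that hold AAATCA, with the mean of its 29 other rearrangements (left), and mean GC content (right), both in percent, by distance in bp from the 3811 summits in steps of 40 bp. At the summit AAATCA reaches 5.64% and the rearrangements 5.79%, and GC content falls to 33.3%.

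Ribosomal protein genes were marked more often than matched genes, and chemosensory receptor genes less often. Neither list passed without the peaks within 500 bp of a transcript start. A reproducible summit lay in the gene or within 5 kb of it for 68 of 92 ribosomal protein genes (73.9%), against 36.1% in random lists matched on length (two-sided permutation test, Benjamini-Hochberg adjusted p = 0.0002 over 20 lists). The unadjusted permutation p, 2e-05, was the smallest that the draws can give. The peak at RpL7 lay 38 bp inside the gene (2L position 10201042, rank 136 of 3811) and that at RpS27 24 bp upstream of it (3R position 25247538, rank 216). The strongest peak in the territory of RpS7 (rank 97) lay nearest to the start of the neighbour CG9743. A summit stood at an own transcript start in 54 of the 92 genes (58.7%). Among the odorant, gustatory and ionotropic receptor genes, 28 of 179 (15.6%) had a summit in their territory, against 41.0% in matched lists (adjusted permutation p = 0.0002), and none had a summit within 500 bp of a start of its own. Matching also on transcript starts, added after the data were seen, gave 43.3% for the ribosomal protein list and 34.9% for the receptor list. Both lists still passed (adjusted permutation p = 0.0002). Of the members with the strongest peaks, Ir25a (rank 41) had its peak nearest to the start of tank, Gr5a (rank 230) to that of Tre1 and Gr61a (rank 427) to that of CG13901; only that of Gr93a (rank 449), 4138 bp upstream, lay nearest to the receptor gene itself.

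None of the other 18 lists passed at an adjusted p of 0.05, and 4 of the 20 had an unadjusted p under 0.05. Proneural and sensory organ precursor genes, among which Senseless is known to act, had a summit in 11 of 23 territories, against 11.4 in matched lists (adjusted permutation p = 1). The Notch pathway and E(spl)/Brd complex list had 15 of 24 against 9.21 (permutation p = 0.0233, adjusted p = 0.116). It passed without replicate 1 (15 of 24 against 7.64, adjusted permutation p = 0.0192). That setting keeps the reproducible peaks found among the strongest of both other replicates, and does not call peaks anew. Its neighbouring members share peaks: with overlapping territories counted once, an alternative added after the data were seen, it had 4 of 11 against 5.43. Neuroblast and central nervous system patterning genes had 4 of 21 against 10.3 (adjusted permutation p = 0.0519). This list passed, below matched genes, in replicate 2 alone (3 of 21, adjusted permutation p = 0.0112) and without replicate 3 (2 of 21, adjusted permutation p = 0.0327), but had 5 against 5.42 with the nearest transcript start. Salivary gland genes had 11 of 16 against 8.48, programmed cell death genes 8 of 12 against 5.5, EGFR pathway genes 12 of 16 against 8.93 and housekeeping genes of the cytoskeleton and translation 10 of 14 against 6.48 (adjusted permutation p from 0.386 to 0.509).

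For the remaining lists, members with a summit numbered 6 of 17 peripheral sensory neuron genes (9.7 matched), 6 of 14 oenocyte genes (7.61), 6 of 10 Hox genes and cofactors (5.88), 6 of 19 segmentation genes (9.13), 12 of 20 mesoderm and muscle genes (10.8), 9 of 13 midgut and fat body genes (6.57) and 9 of 15 hemocyte genes (7.89). They numbered 4 of 13 tracheal genes (6.93), 6 of 11 glial genes (5.67), 6 of 12 epidermis and cuticle genes (6.44) and 7 of 12 germline genes (5.8). The count of lists above matched genes was 1, but it was 4 where each summit went to the gene with the nearest transcript start, which added the Notch and E(spl), EGFR and housekeeping lists. It was 2 with territories of 1 kb, and 0 without the peaks within 500 bp of a transcript start, where ribosomal protein genes stood at 13.04% against 9.15% (adjusted permutation p = 0.484) and chemosensory receptor genes at 6.70% against 10.7% (adjusted permutation p = 0.273). In that setting, salivary gland genes had 10 of 16 against 4.62 (permutation p = 0.00546, adjusted p = 0.0986). Housekeeping genes had 6 of 14 against 1.78 (permutation p = 0.00986, adjusted p = 0.0986). Proneural and sensory organ precursor genes had 10 of 23 against 5.86 (adjusted permutation p = 0.273). Oenocyte genes (3 of 14 against 3.85) and peripheral sensory neuron genes (5 of 17 against 6.14) were among the lists below matched genes. None of the 20 lists passed there.

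**Figure D4:**
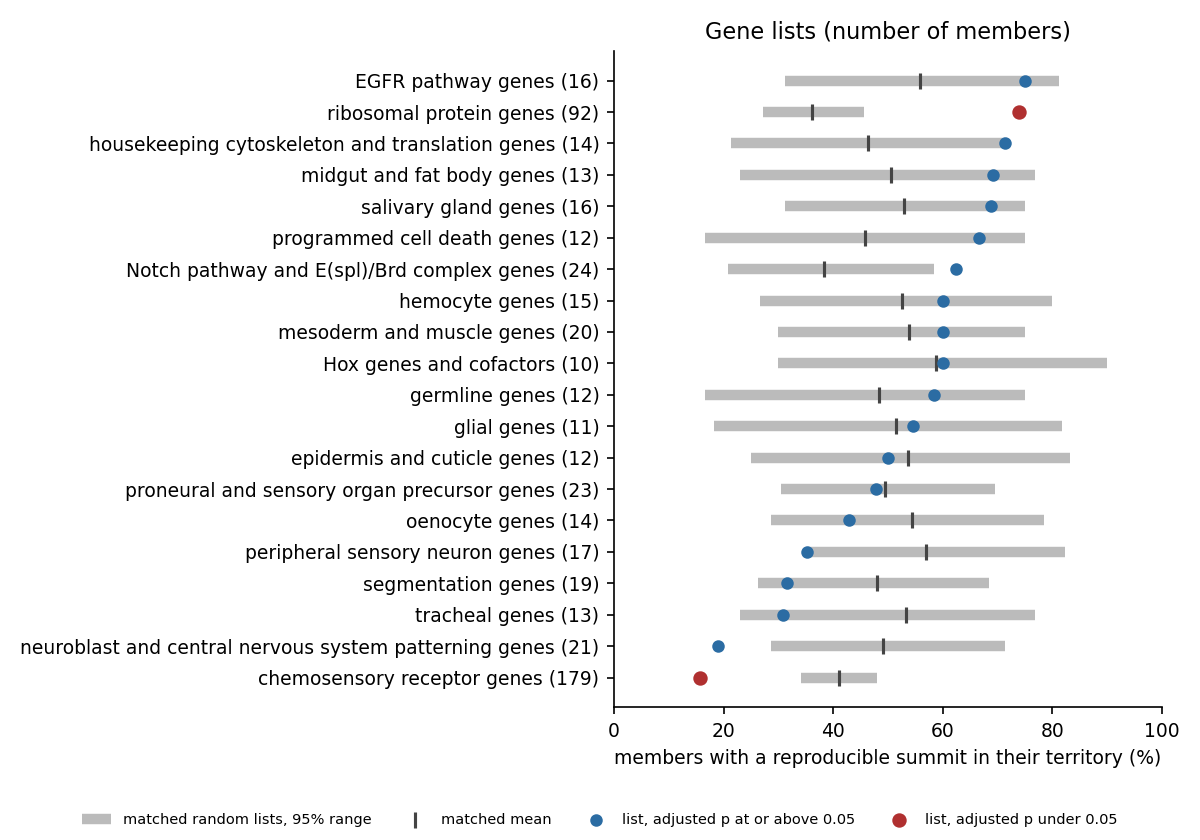
Share of each list's members, in percent, with a reproducible summit in the gene or within 5 kb of it (points), with the mean (ticks) and 95% range (bars) of 100000 random lists matched on length; the number of members stands in parentheses. Ribosomal protein genes (73.9%) lie above their range and chemosensory receptor genes (15.6%) below it; the Notch and E(spl) list (62.5%) and the neuroblast list (19.0%) lie outside theirs but miss the adjusted threshold.

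The gene sens itself carried reproducible peaks, as did the cell death genes hid and rpr and the salivary gland regulators fkh and CrebA. The proneural genes ac, sc and ato and the gene ase did not. Over all protein-coding genes, 5912 of 13945 (42.4%) had a summit in their territory, so having a summit, or none, is common. Around sens (3L, 13396228 to 13401125, minus strand, dm6), 5 summits fell within the gene or 5 kb of it. The strongest, at 13403204, lay 2079 bp upstream of the transcript start with a signal value of 299.2 and rank 1093; another, at 13401071, lay 54 bp inside the gene. No summit fell within 5 kb of the proneural genes ac, sc and ato, of ase or of rho, which encodes a protease that activates EGFR ligands. The strongest pooled peaks in their territories ranked 4884 for rho, 5450 for ase, 14120 for ato and 15353 for sc among 28357, below the reproducible list, and ac had none. The cell death genes hid and rpr each had 1 summit, 350 and 4915 bp upstream, with ranks 409 and 763. The salivary gland regulators fkh and CrebA had 2 and 3 summits; the strongest lay 207 bp upstream of fkh (rank 484) and 2769 bp inside CrebA, in an intron (rank 1483). In the territory of E(spl)m8-HLH, a Notch target, the strongest of 3 summits (rank 145) lay nearest to the start of the neighbour gro.

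In the 50 kb on each side of sens there were 6 reproducible peaks, against a median of 4 for all protein-coding genes. Their summed signal stood at percentile 57.8 of all genes' windows, and from 34.2 to 69.9 in the replicates' own strongest peaks. All 6 lay at most 7334 bp from the transcript start, and with 5 kb on each side, a window chosen after the data were seen, the percentile was 96.1. In that window the median over all protein-coding genes was 0 reproducible peaks, so few peaks give a high percentile. Each window also holds the gene body, so windows differ in length between genes.

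**Figure D5:**
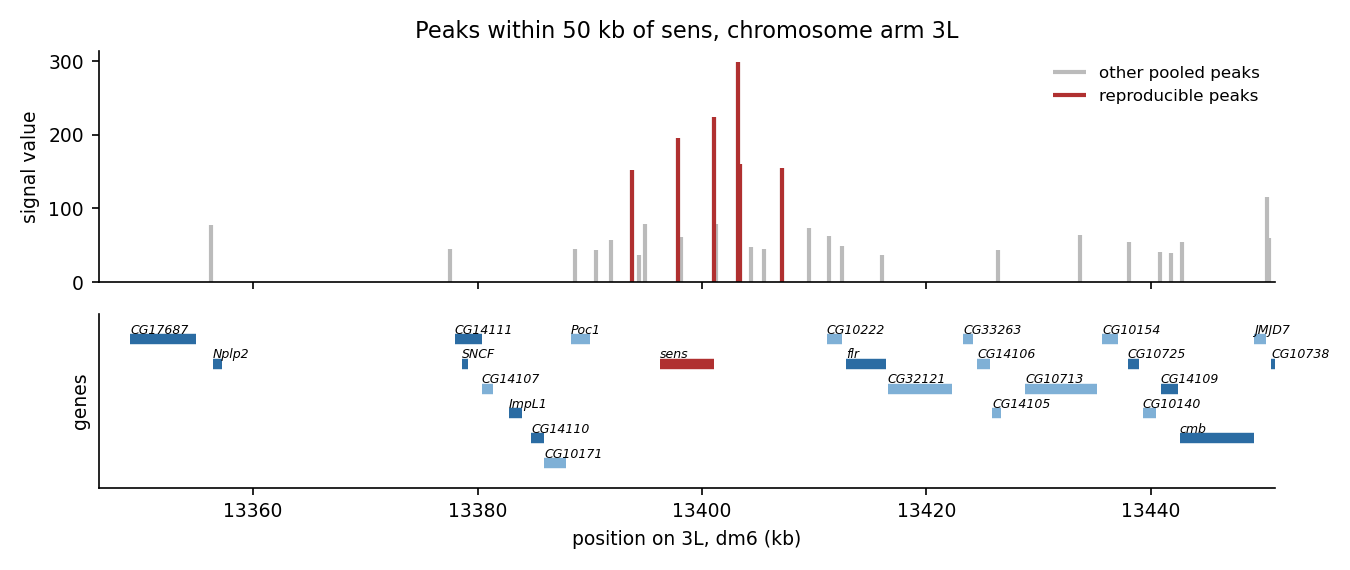
Map of 3L positions 13346228 to 13451125 (dm6) with position in kb on the horizontal axis: signal value of the 6 reproducible peaks and of 23 other pooled peaks (top), and protein-coding genes (bottom; sens in red, other plus-strand genes dark and minus-strand genes light blue). The reproducible peaks gather around sens, the strongest at a signal value of 299.2.

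The X chromosome carried 682 reproducible peaks, 28.97 per Mb, and the large autosome arms 3118, or 28.6 per Mb. The ratio was 1.01, with an exact 95% interval of 0.931 to 1.10 that covers counting error only. Counted within annotated genes alone the ratio was 1.16 (exact binomial p = 0.00283), and in the strongest peaks of replicate 1 alone it was 0.917 (exact binomial p = 0.0482). The genes with most summits were kirre, a myoblast fusion gene of 394149 bp on X, with 18, and CG1677 on X, with 15. They were followed by 4 genes with 11 each: Hr4, a nuclear receptor, and Raf, the MAP kinase kinase kinase, on X, sbb on 2R and ush on 2L.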

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

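Peaks off the main chromosome arms were used in no main comparison, because the dm6 lists and both IDR lists hold none. On dm3, the pooled list held 67 of them, the list of replicate 1 held 89, that of replicate 2 held 73 and that of replicate 3 held 105, which is 0.249% to 0.475% of each replicate's peaks. They were singled out because they are signal in data outside the main measurement, with no control list to set them against. Of the 67 pooled peaks, 56 lay on heterochromatic scaffolds, 7 on unplaced sequence and 4 on the mitochondrial genome, and 5 reached a q-value of 0.01. The strongest of the pooled ones was mitochondrial, with a signal value of 128.6 and rank 4245, below the lowest signal value of the dm3 IDR list, 135.2. In the replicates' own lists the strongest ranked 2220 in replicate 1, on unplaced sequence, 2696 in replicate 2, on the mitochondrial genome, and 3803 in replicate 3, on a heterochromatic scaffold, all within the 3949 peaks that the dm3 IDR list holds. Such peaks therefore entered the alternative overlap of the replicates' strongest peaks on dm3.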

How the results depend on the processing

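Placement at transcript starts kept its direction and stayed past the threshold in every alternative run, from 38.8% with a 250 bp window to 58.6% with 1000 bp, as did the shared peaks of the replicates. The top of the pooled list repeats the IDR list peak for peak and tests nothing. A stricter list, with signal at or above the median, held 1906 peaks by construction. The mean correlation of signal was 0.78 as Pearson's r on log2 signal, and from 0.67 to 0.73 with each replicate left out. The gain of AAATCA over its background was 0.258 percentage points against dinucleotide shuffles, no longer past the threshold; that alternative was added after the data were seen and, by construction, holds base composition fixed. The number of gene lists above matched genes was 2 with territories of 1 kb, 4 with the nearest transcript start and 0 without promoter peaks. It was 1 to 2 where each replicate in turn was left out by keeping only reproducible peaks among the strongest of both others. The X to autosome ratio was 0.917 in replicate 1 alone, the opposite direction, and 1.16 within genes, past the threshold; the cause was not tested. Signal around sens rose to percentile 96.1 with 5 kb on each side, added after the data were seen, since its peaks lie close to the gene. Leaving out the top of the pooled list, calls of single lists were the same in 251 of 260 repeats, gained in 7 and lost in 2. No paired analysis was possible because the series has 1 group. Depth is unknown, so peaks missing from a replicate's strongest cannot be set against its sequencing depth.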

Other observations

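All 8-mers at summits were counted after the data were seen, and the sequences given here were picked and compared on the same windows. At promoter summits TATCGATA, the DNA replication-related element of many housekeeping promoters, was present in 73 of 1855 windows (3.94%), against 0.27% of flanks, and ranked 1 by gain among 592 rearrangements of its letters; the next, ATATCGAT, gained 40 windows. Promoters without peaks were not compared, so its position in promoters enters this gain. At the 1956 summits away from transcript starts it was present in 7. There, CACTGAGA had the highest ratio of summits to flanks among the 339 8-mers seen in at least 40 windows, with 52 windows (2.66%) against 0.204% of flanks, though AATATTTA gained more windows (122 against 37); by the same ratio TATCGATA ranked 3 at promoter summits, behind ATCGATAG and ACTATCGA. Of the CACTGAGA windows, 4 of the 52 were mostly soft-masked repeat sequence, against 7.00% of all such summit windows. A summit lay within 500 bp of an own start in 54 of 92 ribosomal protein genes, 8 of 14 housekeeping genes, 7 of 16 EGFR pathway genes, 6 of 16 salivary gland genes, 4 of 12 cell death genes and 5 of 23 proneural and sensory organ precursor genes. The count was 1 of 21 in neuroblast genes and 0 in the segmentation, Hox, chemosensory, midgut and fat body, and epidermis lists; it was 16.4% over all protein-coding genes, and differences between lists were not tested.

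The EGFR pathway list did not pass, and its members ranged widely: Raf had 11 summits with a highest signal value of 1120, aos had 2 with 1013, S had 5 with 853.8 and spi had 4 with 812.7, while Egfr had 1 with 169.02 and kek1, Sos, rl and rho had none. In the hemocyte list, ush had 11 summits, and the strongest peak of the genome lies inside that gene as well as near cbt. In the muscle list, Mef2 had 6 with a highest value of 1331. Of the sensory organ precursor genes, chn had 3 with 784.1, sens-2 had 1 with 444.8 and ct had 2 with 425.2, while numb, amos, cato and l(1)sc had none. These genes were chosen after their values were seen.

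The tests of GC content in the next paragraph were written before their results were seen but after the placement of peaks was known; the 5 kb window around sens was chosen after its value was seen. The other tests were set before the data were examined.

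The first pattern is the gathering of peaks at transcript starts. GC content does not account for it. Random positions with the GC content of the summits lay at transcript starts in 13.35% of cases, against 48.7% observed. In coding exons they lay in 4.782% of cases, against 0.105% observed and 13.7% of shifted summits. GC content may thus account for part of the low share in coding exons, but not for all of it. Background of the immunoprecipitation at highly transcribed genes may contribute. As that explanation predicts, ribosomal protein genes carried peaks in 73.91% of cases, against 36.1% in lists matched on length. In lists matched also on transcript starts the share was 43.3%. Whether Senseless itself binds at these promoters stays open, as no immunoprecipitation without the fusion protein was analysed here.

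The second pattern is the excess of AAATCA at summits over flanks. Base composition may explain it, since AAATCA ranked 20 among its 30 rearrangements by gain, and each of the other 29 also gained. A gain specific to the core in part of the peaks stays open.

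The third pattern is the group of peaks around sens, where a transgene with extra copies of the region might raise all signal. Over 50 kb on each side the summed signal stood at percentile 57.84, under the bound of 95 set in advance. Over 20 kb it stood at percentile 85.7, also under that bound. How far extra copies would raise these percentiles was not tested, so they cannot decide whether a region that wide is copied. In the nearest 5 kb the summed signal stood at percentile 96.11, and at 96.9, 93.6 and 92.6 in the full lists of replicates 1, 2 and 3. The values of replicates 2 and 3 lie under 95. Extra copies of a short region could still account for the peaks there. Binding of Senseless at its own gene predicts the same, and the extent of the tagged region is not given in the sources used here.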
